A study of Mus musculus with 10 samples.

How the data were processed

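Liver RNA of 9 libraries was analysed, 3 each from control, ASH and AH mice. Per the labels, male C57BL/6J mice ate chow or a solid diet rich in saturated fat and cholesterol for 2 weeks, and a gastric catheter then supplied 60% of calories as a high-fat diet with 36% of calories from corn oil, with chow or the solid diet supplying the other 40%. The ethanol dose was raised over 8 weeks in ethanol-fed mice. Per the labels, total RNA was sequenced as single reads of 50 bases, after TruSeq RNA library preparation. The processing notes name TopHat2 2.0.5, Partek 4 and the mm10 build without saying which did what.

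The deposited count table holds expected counts, which are estimated reads per transcript not scaled to library size, for 94545 transcripts of 38924 genes. Transcripts were summed to genes and rounded to whole reads; 45.7% of gene values above 0 were not whole to within 0.01 reads. Of 10 listed samples, 2 (both of control replicate 3, on lanes 7 and 8) are 1 column in the deposited table, so 9 libraries were used. The authors' table of differential expression gives p values and false discovery rates, ratios of group means, and normalised values of another kind, which are 1 plus the deposited reads times 1 factor per library. Those tables were used to describe the authors' own results and to compare signs, not to make any call. Gene names and coordinates came from GENCODE release M21 for 37607 IDs, and 1251 IDs were not named.

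Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. filterByExpr with a minimum count of 10, a minimum total of 15 and a minimum share of 0.7 left 15228 of 25204 genes with a read. TMM factors were used, all 9 libraries were fitted together with group as the only term, and each contrast was tested by the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 27.1%, the prior degrees of freedom 3.69 and the residual degrees of freedom 6. Values per group are CPM with TMM factors, as mean and SD of 3 libraries, and the SE of a log2 fold change is its size divided by the square root of F. A gene called at 0 reads in a group is given as a bound against a floor of 3 reads over the group, and at 1 to 3 reads as a ratio with a 95% counting interval.

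The 3 comparisons, the test, the 38 gene lists with 682 members, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 7 pathway genes in every comparison, the 8 called genes with the highest and the 8 with the lowest log2 fold change in AH against control (6 and 6 in ASH against control) among genes with an average log2 CPM of at least 2 and no overlap between groups, and up to 4 members of each list with the smallest adjusted p, plus members that went against their list. Lists of at least 5 tested members (36 of 38) were tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation. They were also tested with fry, which tests a list against no change and not against other genes. Both were adjusted over the lists of a comparison. Exocrine pancreas and gut epithelium had too few members for a test. Of the members, 5 matched no gene.

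Alternatives were DESeq2's size factors, upper-quartile factors, library totals, DESeq2's Wald test (version 1.42.0), no filter, a filter of CPM above 1 in at least 3 libraries, a fit of the 2 groups compared, a replicate block, the 20 most abundant genes left out, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each library in turn. Counts of list members with library totals and without each library were added after the data were seen. The overlap of both comparisons with control was set against 50 simulations without group effects (seed 11). Every 3 against 3 split of the libraries of a comparison (10 each) was fitted. The pipeline was tested on simulated changes in 14951 genes: 37% of 2-fold and 74% of 4-fold changes were called, all in the right direction, and 5 of 120 calls were unchanged genes. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.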

Results

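Liver RNA of male C57BL/6J mice was sequenced in 3 groups of 3 libraries: control, alcoholic steatohepatitis (ASH) and alcoholic hepatitis (AH). ASH mice received an ethanol diet through a gastric catheter over 8 weeks. AH mice received part of their ethanol as a weekly binge of 4 to 5 g/kg from week 2, in place of ethanol withheld around it, and control mice received a dextrose bolus of equal calories. Estimated reads per library summed to 21779092, 20305099 and 24753654 in control replicates 1, 2 and 3, to 30184941, 27473045 and 32644807 in ASH replicates 1, 2 and 3, and to 28896395, 18697810 and 29872634 in AH replicates 1, 2 and 3. The labels do not state that each library came from 1 animal, so p-values measure the spread between these libraries. Control replicates 1 and 2 were sequenced on lane 7, control replicate 3 on lanes 7 and 8, and all ASH and AH libraries on lane 8. No control library was on lane 8 alone, so lane and ethanol cannot be told apart. The labels also do not say which groups ate chow and which ate the solid diet rich in saturated fat and cholesterol.

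The first principal component of log2 CPM (counts scaled to the reads of each library) over 15228 tested genes held 58.1% of the variance. The control libraries lay between -115.72 and -64.10 on it, and the ASH and AH libraries between 17.82 and 71.13. On the second component, with 14.9% of the variance, AH replicates 1 and 3 lay at 42.00 and 43.01, the ASH libraries between -55.93 and -25.46, and AH replicate 2 at -3.36. TMM scaling factors were 0.737 to 0.845 in control, 0.964 to 1.04 in ASH, and 1.39, 1.03 and 1.36 in AH replicates 1, 2 and 3.

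**Figure D1:**
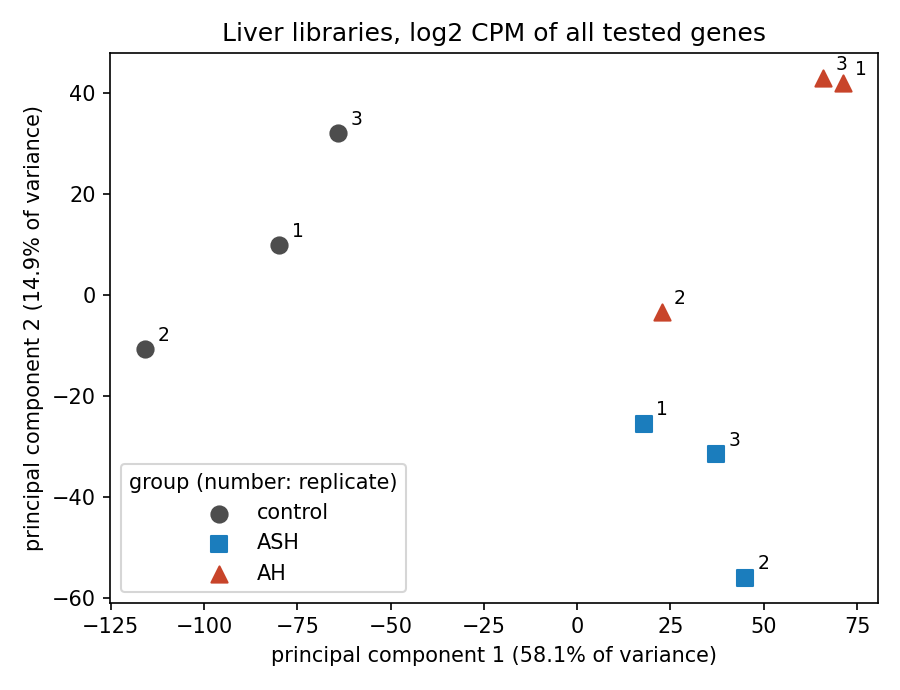
Principal components 1 and 2 of log2 CPM of all tested genes, 1 point per library, with colour and marker for the group and a number for the replicate. Control libraries lay apart from all ASH and AH libraries on component 1 (58.1% of the variance), and AH replicate 2 lay between the ASH libraries and AH replicates 1 and 3 on component 2.

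The comparison of AH with control asked how the liver transcriptome of mice with chronic ethanol and weekly binges differed from that of mice without ethanol, with the caspase and gasdermin pathway of the series title at its centre. Casp4, the mouse caspase that detects bacterial lipopolysaccharide inside cells, rose from 2.58 ± 1.27 CPM in control to 11.2 ± 4.67 CPM in AH (mean ± SD, n = 3 each, log2 fold change 2.11 ± 0.42 SE, adjusted p = 0.00605, edgeR's quasi-likelihood test). Nlrp3, an inflammasome sensor, rose from 0.990 ± 0.569 to 4.46 ± 0.799 CPM (2.14 ± 0.44, adjusted p = 0.00704). Il18, a cytokine precursor cleaved by the caspase encoded by Casp1, fell from 11.9 ± 2.10 to 4.92 ± 1.19 CPM (-1.28 ± 0.23, adjusted p = 0.00452), or by 0.67 with library totals in place of TMM factors (adjusted p = 0.0401). In each of these genes the 3 AH libraries lay on one side of the 3 control libraries. Transcripts of 5055 genes differed, and the members of the fixed lists for macrophages, bile duct cells and matrix were mostly higher in AH while those for cholesterol synthesis and male-biased liver genes were mostly lower.

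Casp1, the caspase that matures interleukin-1 beta, rose from 2.60 ± 1.77 to 7.69 ± 0.0460 CPM (1.54 ± 0.48, adjusted p = 0.0353). Pycard, the inflammasome adaptor, rose from 2.09 ± 1.5 to 7.55 ± 1.87 CPM (1.83 ± 0.54, adjusted p = 0.0285), and Il1b, which encodes interleukin-1 beta, from 4.83 ± 2.51 to 15.4 ± 3.49 CPM (1.66 ± 0.47, adjusted p = 0.0238). Gsdmd, the pore-forming target of these caspases, fell from 43.0 ± 1.49 to 31.7 ± 2.11 CPM (-0.44 ± 0.15, adjusted p = 0.0477). Casp1, Pycard, Il1b and Gsdmd all lay close to the threshold. The adjusted p of Casp1 was over 0.05 with only the 2 groups, without control replicate 1, without ASH replicate 3 and without AH replicate 1 or 3 (0.00650 to 0.0944 over all alternatives). That of Pycard was over 0.05 without control replicate 1 and without AH replicate 1 or 3 (0.00348 to 0.0934 overall). For Il1b it was over 0.05 with a replicate block, without control replicate 2 or 3 and without AH replicate 1 or 3 (0.00255 to 0.0619 overall). For Gsdmd it was over 0.05 with upper-quartile factors, library totals, no filter and a replicate block, without control replicate 1, 2 or 3 and without AH replicate 1, 2 or 3 (0.0177 to 0.357 overall). With library totals its log2 fold change was 0.20 (adjusted p = 0.357).

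On the mm10 build Casp4 (ENSMUSG00000033538.7, chromosome 9, 5308828 to 5336783) lies beside Casp1 (ENSMUSG00000025888.5, chromosome 9, 5298517 to 5307265), a related gene on the same strand. How reads that fit several related or overlapping genes were shared out, and whether strand was used, is not stated, so the split between neighbours such as Casp1 and Casp4 is uncertain.

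**Figure D2:**
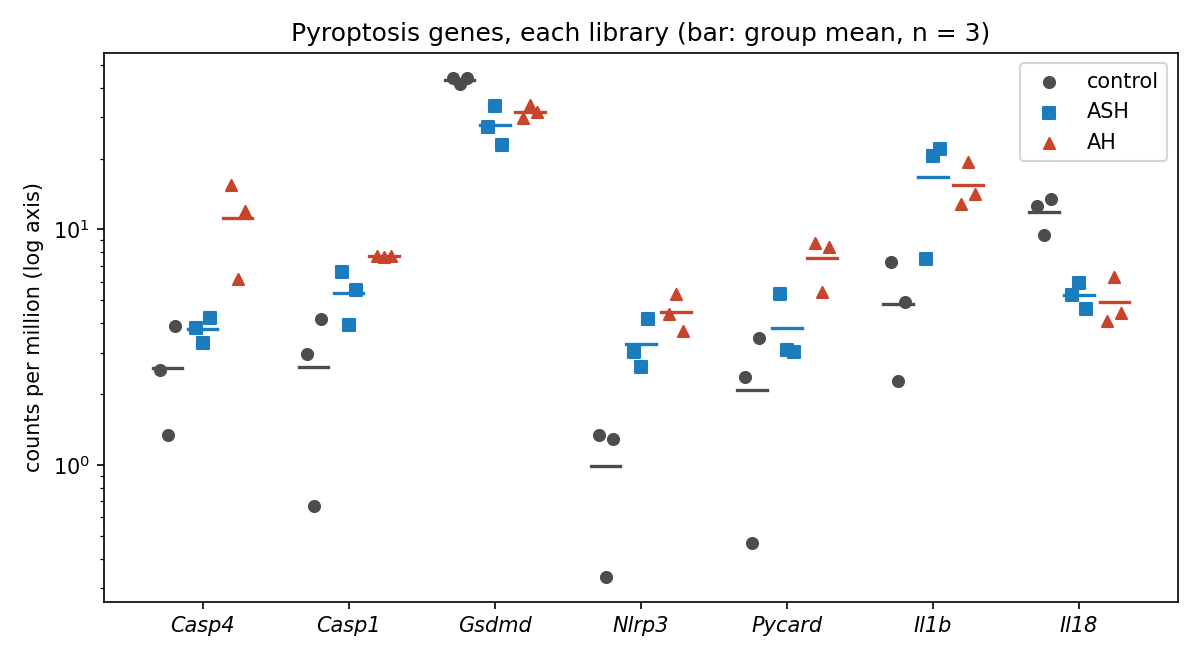
CPM of the 7 pathway genes in each library on a log axis, 1 point per library and a bar for the mean of each group (n = 3). Casp4 averaged 2.58 CPM in control, 3.77 in ASH and 11.2 in AH, while Gsdmd averaged 43.0, 27.9 and 31.7 CPM.

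Of 15228 tested genes, 5055 passed a Benjamini-Hochberg adjusted p under 0.05 by edgeR's quasi-likelihood test, 2670 higher and 2385 lower in AH, and 3089 of them differed at least 2-fold. The 3 libraries of one group lay above all 3 of the other in 53.8% of tested genes, where chance gives 10%. Without AH replicate 1 or 3 the count was 2338 or 2855, and without control replicate 1 or 2 it was 3338 or 3329. With library totals, which put the median of all genes 0.65 higher on the log2 scale, 7945 genes passed and 91.5% of them were higher in AH.

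Among the called genes with the largest rises were several female-biased cytochrome P450 genes. Ly6d, a membrane-anchored surface protein, rose from 1.35 ± 0.572 to 160.4 ± 21.1 CPM (log2 fold change 6.85 ± 0.39 SE, adjusted p = 4.76e-05). Cbr3, a carbonyl reductase, rose by 6.56 ± 0.49 (adjusted p = 0.000152). Fgf21, a hormone released by the liver under metabolic stress, rose by 5.86 ± 0.67 (adjusted p = 0.000875), and Mmp7, a matrix metalloproteinase of epithelial cells, by 6.02 ± 1.30 (adjusted p = 0.00866). The cytochrome P450 genes Cyp2b13, Cyp2b9 and Cyp2a4, more abundant in female than in male mouse liver, rose by log2 8.55, 6.54 and 6.87 (adjusted p = 0.00295, 0.000549 and 0.00181). Vmn2r3, annotated as a vomeronasal receptor, had 0 reads in the control libraries and was at least 311-fold higher in AH, against a floor of 3 reads over the group (adjusted p = 0.00295). Each of these genes was higher in all 3 AH libraries than in any control library, as the rule for naming them required.

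Hsd3b5, Cyp4a12a, Cyp4a12b and Mup7, on the male-biased list, were among the called genes with the largest falls. Hsd3b5, a steroid dehydrogenase of male liver, had 1 read over the 3 AH libraries against 6107 over the control libraries, a ratio of 11346 (95% counting interval 2036 to 448150). Cyp4a12a and Cyp4a12b, male-biased fatty acid hydroxylases, had log2 fold changes of -8.69 ± 0.94 (adjusted p = 0.000684) and -9.08 ± 0.82 (adjusted p = 0.000336). The major urinary protein genes Mup7 and Mup15 had log2 fold changes of -10.06 ± 1.02 (adjusted p = 0.000523) and -10.93 ± 2.03 (adjusted p = 0.00476), and without AH replicate 2 the value of Mup15 was -16.94. Moxd1, a monooxygenase-like gene, had 3 reads in AH against 3271 in control, a ratio of 2026 (693 to 9823). The pseudogene Serpina4-ps1 had 0 reads in AH and was at least 2788-fold lower (adjusted p = 0.00716), and a gene without a symbol, ENSMUSG00000079360.2, had 3 reads against 970 in control, a ratio of 601 (206 to 2913). The intervals cover counting error only. Cyp2b, Cyp2a, Cyp4a and Mup genes belong to families of near-identical copies, so their values may be shared among family members.

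Of the monocyte and macrophage markers, 17 of 18 rose and 1 did not pass (17 rose adjusted over the list alone). For the monocyte list camera gave adjusted p = 4.66e-10 (0.282 with an estimated correlation). Gpnmb and Trem2, markers of lipid-laden macrophages, rose by log2 5.81 (adjusted p = 0.00264) and 3.13 (adjusted p = 0.00370), and Adgre1, which encodes F4/80, by 2.83 (adjusted p = 0.00321). Of the stellate cell and matrix genes, 21 of 21 rose (21 rose adjusted over the list alone). For the stellate cell list camera gave adjusted p = 4.44e-13 (0.282 with an estimated correlation). Among them were the collagen genes Col1a2 (3.71, adjusted p = 0.00192), Col3a1 (3.68, adjusted p = 0.00195) and Col4a1 (2.44, adjusted p = 0.00192), and the collagen cross-linking enzyme Loxl2 (2.72, adjusted p = 0.00162). Of the cholangiocyte and progenitor markers, 11 of 12 rose and 1 did not pass (11 rose adjusted over the list alone). For the cholangiocyte list camera gave adjusted p = 2.46e-05 (0.388 with an estimated correlation). Epcam, an adhesion protein of biliary and progenitor cells, rose by log2 3.60 ± 0.71 (adjusted p = 0.00594), Prom1 by 4.30 ± 0.74 (adjusted p = 0.00363), Sox9 by 1.64 ± 0.33 (adjusted p = 0.00632) and the keratin gene Krt23 by 3.35 ± 0.53 (adjusted p = 0.00268). Matrix, bile duct and macrophage markers rose in the same libraries in which hepatocyte markers were lower.

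Of the Kupffer cell markers, 8 of 14 rose, 1 fell and 5 did not pass (8 rose and 1 fell adjusted over the list alone). For the Kupffer cell list camera gave adjusted p = 0.00921 (0.462 with an estimated correlation). Marco, a scavenger receptor, and Cd5l rose by log2 2.97 (adjusted p = 0.00551) and 2.30 (adjusted p = 0.00487), and the complement gene C6, also on the male-biased list, went against them (-2.31, adjusted p = 0.00264). The Kupffer cell list was not called with only the 2 groups and without AH replicate 2 (adjusted p = 0.000608 to 0.165 overall). Of the sinusoidal and vascular endothelial markers, 6 of 14 rose and 8 did not pass (7 rose adjusted over the list alone), led by the junction gene Cdh5 (1.55, adjusted p = 0.00939) and the hyaluronan receptor gene Lyve1 (2.62, adjusted p = 0.00956). For the sinusoidal list camera gave adjusted p = 0.000690 (0.462 with an estimated correlation). The endothelial count was 13 with library totals, 2 without control replicate 1, 3 without control replicate 2, 2 without AH replicate 1 and 3 without AH replicate 3. Of the chemokine, cytokine and adhesion genes, 13 of 21 rose and 8 did not pass (14 rose adjusted over the list alone). For the chemokines list camera gave adjusted p = 6.98e-05 (0.282 with an estimated correlation). Icam1 and Sele, which bind leukocytes to endothelium, rose by log2 1.25 (adjusted p = 0.00107) and 5.08 (adjusted p = 0.00469), and the neutrophil attractant Cxcl5 by 2.92 (adjusted p = 0.00321). The chemokine count was 6 without control replicate 1 and 6 without AH replicate 1 or 3, and library totals gave 1.91 for Icam1. None of 17 neutrophil markers passed edgeR's test, 2 had an unadjusted p under 0.05, and 2 passed DESeq2's test. The neutrophil count was 3 higher with library totals, 6 higher without control replicate 3, 1 higher without ASH replicate 2 and 1 higher without AH replicate 2.

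Of the 24 measured pyroptosis and inflammasome genes, 12 rose, 2 fell and 10 did not pass (14 rose and 2 fell adjusted over the list alone). For the pyroptosis list camera gave adjusted p = 0.000628 (0.388 with an estimated correlation). Beside the pathway genes above, Panx1, a membrane channel, rose by log2 2.84 ± 0.39 (adjusted p = 0.00181), and Naip2, a sensor of bacterial proteins, by 1.6 ± 0.27 (adjusted p = 0.00343). Il18 and Gsdmd fell. The count of called members was 20 higher and 1 lower with library totals, 7 without AH replicate 1 and 9 without AH replicate 3.

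**Figure D3:**
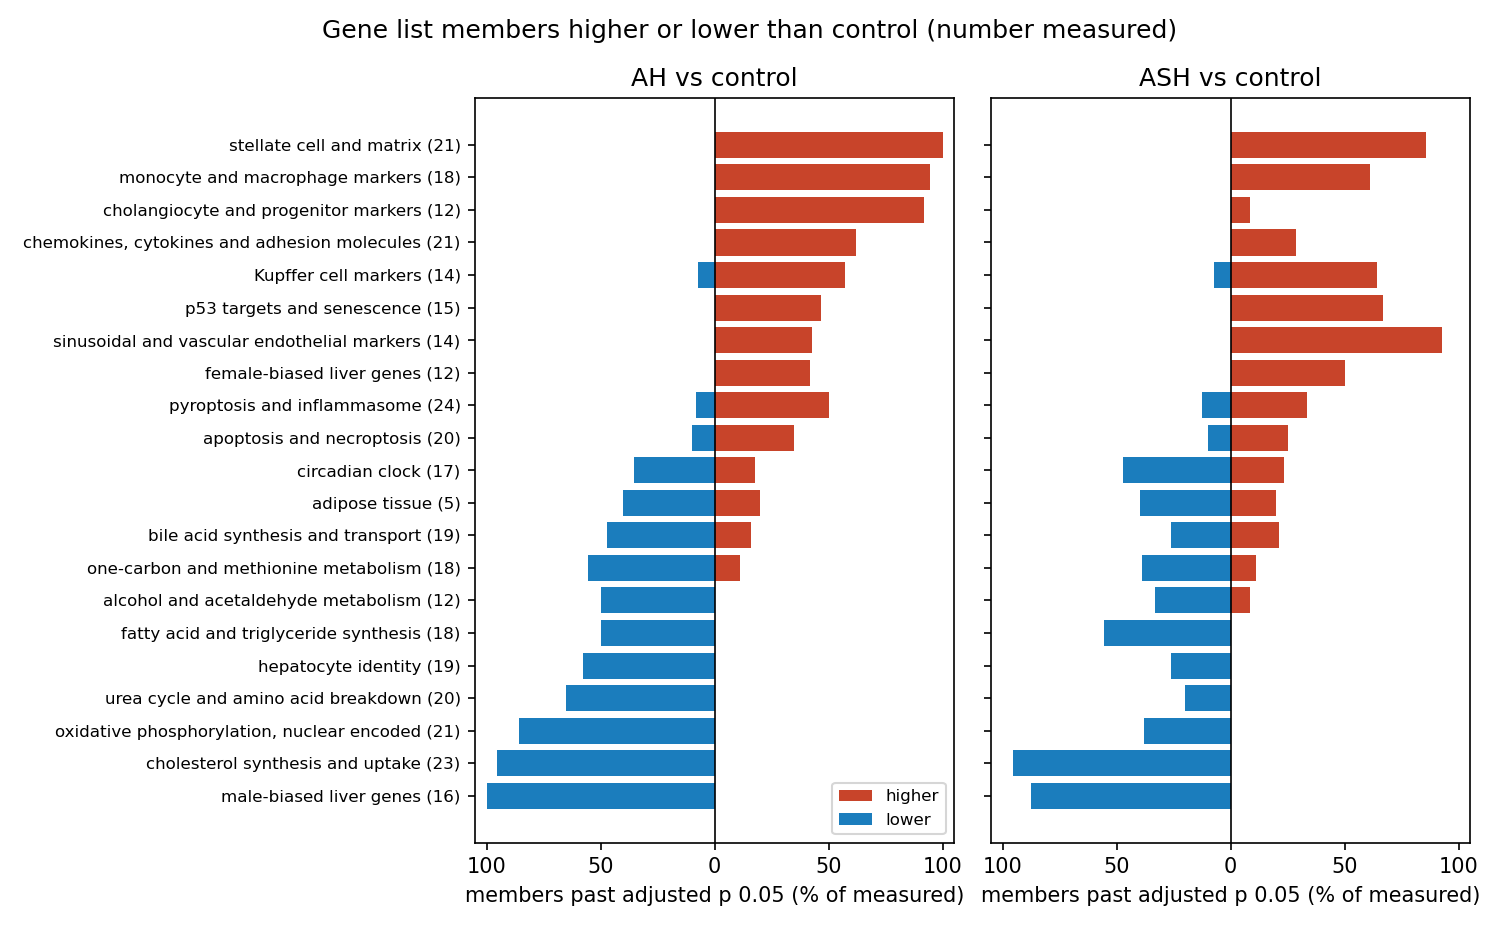
Percent of measured members of each gene list that passed an adjusted p under 0.05, higher (right) or lower (left) than control, for AH and for ASH, with the number measured beside each name. The 21 lists shown are those of the 36 tested lists with at least 40% of members past the threshold in AH, a choice made after the data were seen, and cholesterol synthesis genes were lower in 22 of 23 members in both comparisons.

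Of the cholesterol synthesis and uptake genes, 22 of 23 fell and 1 did not pass (22 fell adjusted over the list alone). For the cholesterol synthesis list camera gave adjusted p = 7.84e-47 (0.0375 with an estimated correlation). Msmo1 and Nsdhl, which demethylate sterols, fell from 341 ± 43.0 to 18.2 ± 4.42 CPM (log2 fold change -4.22 ± 0.23 SE, adjusted p = 4.76e-05) and from 113 ± 27.5 to 6.04 ± 1.21 CPM (-4.21 ± 0.23, adjusted p = 4.76e-05). Cyp51, the lanosterol demethylase, and Hmgcs1, an early enzyme of the mevalonate pathway, had log2 fold changes of -3.78 ± 0.21 (adjusted p = 4.76e-05) and -3.17 ± 0.19 (adjusted p = 4.91e-05). Of the fatty acid and triglyceride synthesis genes, 9 of 18 fell and 9 did not pass (9 fell adjusted over the list alone). For the fatty acid list camera gave adjusted p = 0.000228 (0.315 with an estimated correlation). They included Fasn, the fatty acid synthase (-1.80, adjusted p = 0.00637), Acacb (-2.90, adjusted p = 0.00484), Fads1, a desaturase (-1.39, adjusted p = 0.00248), and Thrsp, a regulator of lipogenesis (-4.23, adjusted p = 0.00352). With library totals the values were -1.14 for Fasn and -0.74 for Fads1. Of the lipid droplet and storage genes, 4 of 14 rose, 1 fell and 9 did not pass (4 rose and 1 fell adjusted over the list alone). For the lipid droplet list camera gave adjusted p = 0.229 (0.551 with an estimated correlation). The fatty acid transporter Cd36 rose by log2 2.48 (adjusted p = 0.000198) and the fatty acid binding protein Fabp4 by 2.39 (adjusted p = 0.00317), whereas Cideb went against them (-0.85, adjusted p = 0.00629, and -0.21, adjusted p = 0.202 with library totals, 2.04e-05 to 0.202 overall). The lipid droplet count was 3 without control replicate 1, 2 or 3 and 3 without AH replicate 1 or 3.

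Of the male-biased liver genes, 16 of 16 fell (16 fell adjusted over the list alone). For the male-biased liver list camera gave adjusted p = 1.14e-24 (0.0587 with an estimated correlation). Of the female-biased liver genes, 5 of 12 rose and 7 did not pass (5 rose adjusted over the list alone). For the female-biased liver list camera gave adjusted p = 0.00139 (0.315 with an estimated correlation). Slco1a1, an organic anion transporter, fell from 264 ± 86.9 to 1.25 ± 0.680 CPM (log2 fold change -7.70 ± 0.52 SE, adjusted p = 8.09e-05), and Nudt7, a peroxisomal coenzyme A hydrolase, from 799 ± 55.0 to 56.2 ± 2.41 CPM (-3.83 ± 0.25, adjusted p = 8.09e-05). Cyp4a14, on the female-biased list, rose by log2 2.28 ± 0.42 (adjusted p = 0.00474). Of the bile acid synthesis and transport genes, 3 of 19 rose, 9 fell and 7 did not pass (3 rose and 9 fell adjusted over the list alone). For the bile acid synthesis list camera gave adjusted p = 0.00306 (0.462 with an estimated correlation). Cyp7b1 and Cyp27a1, enzymes of the alternative pathway of bile acid synthesis, had log2 fold changes of -3.50 (adjusted p = 0.00251) and -1.87 (adjusted p = 0.00345). The members that rose were the export pumps Abcc4 (4.79, adjusted p = 0.000928) and Abcb4 (0.93, adjusted p = 0.00773) and the acyltransferase Acnat1 (0.86, adjusted p = 0.0181). The adjusted p of Acnat1 was over 0.05 without control replicate 1 or 3 and without AH replicate 1 (0.00178 to 0.0721 overall). The bile acid count was 5 higher and 7 lower with library totals and 7 without AH replicate 1, and library totals gave 1.57 for Abcb4 and 1.52 for Acnat1.

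Of the hepatocyte identity genes, 11 of 19 fell and 8 did not pass (13 fell adjusted over the list alone), among them the lipoprotein gene Apoa1 (-1.87, adjusted p = 0.00219), the thyroid hormone carrier Ttr (-1.65, adjusted p = 0.00690) and Fah, an enzyme of tyrosine breakdown (-1.44, adjusted p = 0.00209). For the hepatocyte identity list camera gave adjusted p = 4.22e-06 (0.255 with an estimated correlation). The hepatocyte count was 1 higher and 4 lower with library totals, 7 without control replicate 1, 2 or 3, 5 without AH replicate 1 and 6 without AH replicate 3. Of the urea cycle and amino acid breakdown genes, 13 of 20 fell and 7 did not pass (16 fell adjusted over the list alone), including Otc of the urea cycle (-1.07, adjusted p = 0.00872), Hpd (-1.40, adjusted p = 0.00546) and Prodh (-2.20, adjusted p = 0.00641). For the urea cycle list camera gave adjusted p = 1.63e-06 (0.315 with an estimated correlation). The urea cycle count was 6 with library totals and 7 without AH replicate 1 or 3. Of the nuclear genes of oxidative phosphorylation, 18 of 21 fell and 3 did not pass (19 fell adjusted over the list alone), with Ndufa4 at log2 -1.15 (adjusted p = 0.00434) and Cox7a2 at -0.94 (adjusted p = 0.00267) (-0.28, adjusted p = 0.169 with library totals, 2.62e-08 to 0.169 overall). For the oxidative phosphorylation list camera gave adjusted p = 1.37e-07 (0.366 with an estimated correlation). The oxidative phosphorylation count was 1 with library totals and 10 without AH replicate 1 or 3. Of the alcohol and acetaldehyde metabolism genes, 6 of 12 fell and 6 did not pass (6 fell adjusted over the list alone), including the alcohol dehydrogenases Adh4 (-2.25, adjusted p = 0.00680) and Adh7 (-2.04, adjusted p = 0.00237) and the acetate-activating enzyme Acss2 (-3.19, adjusted p = 0.00224). For the alcohol list camera gave adjusted p = 0.00227 (0.366 with an estimated correlation). Of the one-carbon and methionine genes, 2 of 18 rose, 10 fell and 6 did not pass (2 rose and 10 fell adjusted over the list alone). For the one-carbon list camera gave adjusted p = 0.00534 (0.366 with an estimated correlation). Shmt1 (-1.58, adjusted p = 0.00182) and Pemt, which makes phosphatidylcholine (-1.30, adjusted p = 0.00267), fell, whereas the mitochondrial folate enzyme Mthfd2 (2.14, adjusted p = 0.00268) rose. The alcohol count was 2 higher and 5 lower with library totals. The one-carbon count was 4 higher and 5 lower with library totals. With library totals the log2 fold changes were -1.21 for Apoa1, -1.07 for Ttr, -0.82 for Fah, -0.47 for Otc, -0.81 for Hpd, -0.54 for Ndufa4, -0.96 for Shmt1 and -0.68 for Pemt. In these same libraries macrophage and matrix markers rose.

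Of the NRF2 antioxidant genes, 7 of 18 rose and 11 did not pass (10 rose adjusted over the list alone). For the NRF2 antioxidant list camera gave adjusted p = 1.92e-05 (0.255 with an estimated correlation). Slc7a11, the cystine transporter, rose from 2.39 ± 0.149 to 52.1 ± 0.910 CPM (log2 fold change 4.44 ± 0.30 SE, adjusted p = 8.09e-05), and Nqo1 and Srxn1 rose by log2 2.12 (adjusted p = 0.00118) and 2.93 (adjusted p = 0.00193). Of the p53 targets and senescence genes, 7 of 15 rose and 8 did not pass (9 rose adjusted over the list alone), led by Phlda3 (3.67, adjusted p = 0.000257), Ccng1 (1.10, adjusted p = 0.00137) and Eda2r (3.22, adjusted p = 0.00194). For the p53 targets list camera gave adjusted p = 9.08e-06 (0.255 with an estimated correlation). The NRF2 count was 14 with library totals, and the p53 count 13 with library totals. Of the cell cycle genes, 10 of 26 rose and 16 did not pass (15 rose adjusted over the list alone), with Ccnd1, the D-type cyclin of the start of the cycle, at log2 1.86 (adjusted p = 0.00786) and the mitotic kinase Aurkb at 2.17 (adjusted p = 0.0169). For the cell cycle list camera gave adjusted p = 0.000228 (0.512 with an estimated correlation). The adjusted p of Aurkb was over 0.05 without control replicate 1 or 2 and without AH replicate 1 (0.00101 to 0.0751 overall). The cell cycle count was 23 with library totals, 1 without control replicate 1, 2 without control replicate 2, 17 without control replicate 3, 1 without AH replicate 1 and 2 without AH replicate 3. Of the circadian clock genes, 3 of 17 rose, 6 fell and 8 did not pass (3 rose and 10 fell adjusted over the list alone). For the circadian clock list camera gave adjusted p = 0.0473 (0.315 with an estimated correlation). Arntl (3.00, adjusted p = 0.00230), Npas2 (7.07, adjusted p = 0.00694) and Clock (1.24, adjusted p = 0.00876), partners in the activating complex, rose, whereas the repressor Per3 fell (-2.54, adjusted p = 0.00560). The clock count was 5 without AH replicate 1, and library totals gave 1.75 for Ccng1 and 1.89 for Clock. The clock list was not called with DESeq2, with the CPM filter, without ASH replicate 1 and without AH replicate 1 (adjusted p = 0.00171 to 0.132 overall).

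Xenobiotic metabolism had 3 of 25 members higher and 4 lower (2 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0473, adjusted p = 0.772 with an estimated correlation) and a median that was positive with library totals, and its count was 5 higher and 3 lower with library totals, 3 without control replicate 1 or 2 and 18 without AH replicate 2. Camera did not call it with DESeq2, with the CPM filter, with only the 2 groups, without ASH replicate 1 or 2 and without AH replicate 1 or 3 (adjusted p = 1.61e-08 to 0.254 overall). Mitochondrially encoded genes had 2 of 13 members lower (8 fell adjusted over the list alone, camera adjusted p = 0.000581, adjusted p = 0.462 with an estimated correlation), and the count was 0 with library totals, 0 without control replicate 1, 2 or 3, 1 without ASH replicate 1, 0 without ASH replicate 3, 0 without AH replicate 1, 13 without AH replicate 2 and 0 without AH replicate 3. Camera did not call the other lists. Fatty acid oxidation had 4 of 22 members higher and 4 lower, among them Fabp1, a fatty acid carrier of hepatocytes, which fell by log2 2.55 (adjusted p = 0.000451). Endoplasmic reticulum (ER) and integrated stress had 3 of 20 members higher and 1 lower, among them Trib3 (3.48, adjusted p = 0.000585) and Atf3 (3.81, adjusted p = 0.00434), targets of the integrated stress response, which rose. Acute phase proteins had 2 of 22 members higher and 1 lower, with the interleukin-1 receptor antagonist Il1rn (2.61, adjusted p = 0.00781) and the iron-carrier binding protein Lcn2 (2.02, adjusted p = 0.0110) rising. Apoptosis and necroptosis had 7 of 20 members higher and 2 lower, interferon-stimulated genes 3 of 22 members higher and 1 lower, glycolysis and gluconeogenesis 4 of 19 members higher and 3 lower, immediate early and hypoxia genes 4 of 17 members higher and 2 lower, heat shock proteins 3 of 12 members lower and lymphocyte markers 1 of 17 members lower. Of possible other tissues, red blood cell genes had 1 of 5 members lower, exocrine pancreas 1 of 2 members lower, adipose tissue 1 of 5 members higher and 2 lower and gut epithelium 1 of 3 members lower. The number of called members was 9 higher and 1 lower for fatty acid oxidation, 7 higher and 1 lower for ER stress, 4 higher and 1 lower for acute phase proteins, 12 higher and 1 lower for apoptosis, 10 higher and 0 lower for interferon genes, 9 higher and 0 lower for glycolysis, 9 higher and 1 lower for immediate early genes, 2 higher and 0 lower for heat shock proteins, 2 higher and 0 lower for lymphocyte markers and 4 higher and 1 lower for red blood cell with library totals, and 4 for fatty acid oxidation, 3 for glycolysis and 0 for heat shock proteins without control replicate 1. The number was 5 for fatty acid oxidation, 2 for immediate early genes and 1 higher and 0 lower for heat shock proteins without control replicate 2, and 2 higher and 1 lower for red blood cell without control replicate 3. Called members numbered 4 for fatty acid oxidation, 2 for ER stress, 2 for apoptosis, 1 for interferon genes, 3 for glycolysis, 2 for immediate early genes, 0 for heat shock proteins, 0 for lymphocyte markers and 0 for red blood cell without AH replicate 1, and 7 for acute phase proteins, 1 higher and 0 lower for heat shock proteins and 0 for lymphocyte markers without AH replicate 2. It was 3 for fatty acid oxidation, 4 for apoptosis, 2 for interferon genes, 4 for glycolysis, 1 for heat shock proteins and 0 for red blood cell without AH replicate 3, and 1 higher and 1 lower for lymphocyte markers without ASH replicate 1. The number was 1 higher and 2 lower for lymphocyte markers without ASH replicate 2, and 5 for fatty acid oxidation, 1 for heat shock proteins and 0 for lymphocyte markers without ASH replicate 3. Leaving out 1 library gained camera calls for neutrophil and heat shock proteins without control replicate 3, and adipose tissue without AH replicate 2. The other alternatives gained adipose tissue. Adjusted over the list alone the counts of lists camera did not call differed for fatty acid oxidation (5 rose and 4 fell), apoptosis (7 rose and 3 fell), glycolysis (5 rose and 3 fell), immediate early (5 rose and 2 fell), heat shock proteins (5 fell), lymphocyte (0 passed), adipose tissue (1 rose and 3 fell) and gut epithelium (3 fell).

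Camera called 23 of 36 tested lists, 11 higher and 12 lower. With an estimated correlation 1 list passed, cholesterol synthesis and uptake, and fry found 22 lists moving one way and 33 changing in either direction. The lymphocyte median was 0.15 with a mean of -0.06, fatty acid oxidation had a median of -0.24 with a mean of 0.14, and ER stress a median of -0.15 with a mean of 0.21. Camera's direction for ER stress, which did not pass, was higher, against its median. The medians of acute phase, ER stress, fatty acid oxidation, heat shock and xenobiotic genes were positive with library totals.

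ASH against control set ethanol without binges against a dextrose bolus and no ethanol. Nlrp3 rose from 0.990 ± 0.569 to 3.27 ± 0.805 CPM (mean ± SD, n = 3 each, log2 fold change 1.70 ± 0.44 SE, adjusted p = 0.0185, edgeR's quasi-likelihood test), and Il1b rose from 4.83 ± 2.51 to 16.6 ± 7.99 CPM (1.78 ± 0.47, adjusted p = 0.0202). Gsdmd fell from 43.0 ± 1.49 to 27.9 ± 5.37 CPM (-0.63 ± 0.15, adjusted p = 0.0149), and Il18 from 11.9 ± 2.10 to 5.25 ± 0.668 CPM (-1.18 ± 0.23, adjusted p = 0.00684). In these 4 genes no ASH library overlapped the control libraries. Casp4 averaged 3.77 ± 0.449 CPM in ASH and did not pass (0.53 ± 0.41, adjusted p = 0.341), nor did Casp1 (1.02 ± 0.48, adjusted p = 0.132) or Pycard (0.84 ± 0.54, adjusted p = 0.256). These 3 values were 0.25, 0.60 and 0.40 without control replicate 2 and 0.96, 1.54 and 1.40 without control replicate 3, and that of Pycard was 0.52 without ASH replicate 1. Library totals gave 0.84 for Casp4. The adjusted p of Nlrp3 was over 0.05 without ASH replicate 3 (0.000519 to 0.0656 overall). That of Il1b was over 0.05 with a replicate block, without control replicate 2 or 3 and without ASH replicate 2 or 3 (0.00133 to 0.0702 overall), and that of Gsdmd over 0.05 with library totals and without ASH replicate 3 (0.00189 to 0.207 overall). With library totals the Gsdmd value was -0.30 (adjusted p = 0.207).

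By edgeR's quasi-likelihood test 4668 of 15228 genes passed an adjusted p under 0.05 in ASH, 2520 higher and 2148 lower, and 2694 of them differed at least 2-fold. The libraries of the groups did not overlap in 47.5% of tested genes, where chance gives 10%. Without control replicate 1 or 2 the count was 2898 or 3095, and without ASH replicate 2 or 3 it was 3004 or 2716. Library totals put the median of all genes 0.32 higher, and 81.8% of the 4813 genes then called were higher in ASH. Cyp2b13 and Cyp2b9 rose by log2 9.15 ± 1.38 (adjusted p = 0.00254) and 7.31 ± 0.69 (adjusted p = 0.000421), Ly6d by 6.18 ± 0.38 (adjusted p = 6.68e-05) and Cbr3 by 6.15 ± 0.49 (adjusted p = 0.000199). Ackr3, a scavenging chemokine receptor, rose by 5.70 ± 1.2 (adjusted p = 0.00866). Vmn2r3 had 0 reads in control and was at least 50.9-fold higher in ASH (adjusted p = 0.01). Hsd3b5 and Serpina4-ps1 had 0 reads in ASH and were at least 3438-fold and 2535-fold lower (adjusted p = 0.000153 and 0.00808). Moxd1 had a log2 fold change of -9.92 ± 0.67 (adjusted p = 9.75e-05), Tff3, a trefoil peptide, of -9.73 ± 1.02 (adjusted p = 0.000591), the acetylcholine receptor subunit gene Chrna4 of -9.43 ± 1.35 (adjusted p = 0.00207), and Cyp4a12b of -8.00 ± 0.76 (adjusted p = 0.000421). All of these genes were on 1 side of the control libraries in 3 of 3 ASH libraries.

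Of the cholesterol synthesis and uptake genes in ASH, 22 of 23 fell and 1 did not pass (22 fell adjusted over the list alone). For the cholesterol synthesis list camera gave adjusted p = 2.96e-58 (0.0317 with an estimated correlation). Cyp51 fell from 211 ± 23.2 to 9.32 ± 1.27 CPM (log2 fold change -4.50 ± 0.22 SE, adjusted p = 2.89e-05), and Msmo1, Nsdhl and Hmgcs1 had log2 fold changes of -4.47 (adjusted p = 2.89e-05), -4.50 (adjusted p = 2.89e-05) and -3.47 (adjusted p = 2.99e-05). Of the fatty acid and triglyceride synthesis genes, 10 of 18 fell and 8 did not pass (10 fell adjusted over the list alone), among them Fasn (-2.76, adjusted p = 0.00165), Fads1 (-2.02, adjusted p = 0.000629), the lipogenic transcription factor Srebf1 (-2.21, adjusted p = 0.00173) and Mid1ip1, which activates acetyl-CoA carboxylase (-2.77, adjusted p = 0.00189). For the fatty acid list camera gave adjusted p = 8.32e-07 (0.283 with an estimated correlation). Of the lipid droplet and storage genes, 6 of 14 rose, 1 fell and 7 did not pass (6 rose and 1 fell adjusted over the list alone). For the lipid droplet list camera gave adjusted p = 0.00220 (0.330 with an estimated correlation). Cd36 (2.74, adjusted p = 0.000127), Fabp4 (2.96, adjusted p = 0.00165) and the droplet protein gene Cidec (4.03, adjusted p = 0.0101) rose. Of the male-biased liver genes, 14 of 16 fell and 2 did not pass (15 fell adjusted over the list alone). For the male-biased liver list camera gave adjusted p = 7.06e-21 (0.0577 with an estimated correlation). Of the female-biased liver genes, 6 of 12 rose and 6 did not pass (6 rose adjusted over the list alone). For the female-biased liver list camera gave adjusted p = 0.000333 (0.330 with an estimated correlation). Slco1a1 (-7.65, adjusted p = 9.75e-05) and Nudt7 (-3.82, adjusted p = 9.75e-05) fell, and Cyp2a4 (5.53, adjusted p = 0.00321) and Cyp4a14 (2.48, adjusted p = 0.00401) rose. The number of called members was 4 for lipid droplets without control replicate 3.

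Of the stellate cell and matrix genes in ASH, 18 of 21 rose and 3 did not pass (18 rose adjusted over the list alone), with Loxl2 at log2 2.81 (adjusted p = 0.00148), Col4a1 at 2.51 (adjusted p = 0.00176), the muscle filament gene Des at 1.83 (adjusted p = 0.00302) and the pericyte marker Rgs5 at 1.86 (adjusted p = 0.00500). For the stellate cell list camera gave adjusted p = 1.38e-10 (0.330 with an estimated correlation). Of the sinusoidal and vascular endothelial markers, 13 of 14 rose and 1 did not pass (14 rose adjusted over the list alone). For the sinusoidal list camera gave adjusted p = 2.84e-09 (0.330 with an estimated correlation). Lyve1 rose by log2 3.75 ± 0.60 (adjusted p = 0.00305), Pecam1 by 2.64 ± 0.46 (adjusted p = 0.00421), Cdh5 by 2.01 ± 0.35 (adjusted p = 0.00408) and Tek, the angiopoietin receptor gene, by 2.22 ± 0.40 (adjusted p = 0.00457). Of the monocyte and macrophage markers, 11 of 18 rose and 7 did not pass (13 rose and 1 fell adjusted over the list alone), with Gpnmb (4.50, adjusted p = 0.00622), Adgre1 (2.72, adjusted p = 0.00402), Cd14 (4.12, adjusted p = 0.00463) and Cd68 (1.99, adjusted p = 0.00810) rising. For the monocyte list camera gave adjusted p = 2.61e-05 (0.494 with an estimated correlation). Of the Kupffer cell markers, which share Cdh5 with the endothelial list, 9 of 14 rose, 1 fell and 4 did not pass (10 rose and 2 fell adjusted over the list alone). For the Kupffer cell list camera gave adjusted p = 0.00220 (0.505 with an estimated correlation). Marco (3.26, adjusted p = 0.00457) and Cd5l (2.18, adjusted p = 0.00669) rose and C6 fell (-2.17, adjusted p = 0.00346). The number of called members was 7 for macrophage markers without control replicate 1, and 7 for macrophage markers without ASH replicate 2. The number was 6 for macrophage markers and 6 for Kupffer cell markers without ASH replicate 3.

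Of the chemokine, cytokine and adhesion genes in ASH, 6 of 21 rose and 15 did not pass (7 rose adjusted over the list alone), led by Icam1 (1.35, adjusted p = 0.000793), Sele (4.97, adjusted p = 0.00604) and Cxcl16 (1.27, adjusted p = 0.0151). For the chemokines list camera gave adjusted p = 0.00578 (0.481 with an estimated correlation). Of the pyroptosis and inflammasome genes, 8 of 24 rose, 3 fell and 13 did not pass (10 rose and 4 fell adjusted over the list alone). For the pyroptosis list camera gave adjusted p = 0.0446 (0.743 with an estimated correlation). Beside the pathway genes, the cytokine gene Il1a rose by log2 1.85 (adjusted p = 0.00504), Nek7, a partner of NLRP3, by 0.84 (adjusted p = 0.0130), and the lipopolysaccharide receptor gene Tlr4 by 1.73 (adjusted p = 0.0138). Gsdme, another gasdermin, fell (-0.51, adjusted p = 0.0407). Its adjusted p was over 0.05 with library totals, no filter, only the 2 groups and a replicate block, without control replicate 1, 2 or 3, without ASH replicate 1, 2 or 3 and without AH replicate 1 or 3 (0.0136 to 0.488 overall), and with library totals its value was -0.18. The pyroptosis list was not called by camera with library totals, with DESeq2, with the CPM filter, with only the 2 groups, without control replicate 2, without ASH replicate 2 and without AH replicate 2 (adjusted p = 0.00409 to 0.155 overall). Of the p53 targets and senescence genes, 10 of 15 rose and 5 did not pass (10 rose adjusted over the list alone), with Cdkn1a, the p21 cell cycle inhibitor, at log2 5.01 (adjusted p = 0.00207), Phlda3 at 2.35 (adjusted p = 0.00144), Zmat3 at 1.58 (adjusted p = 0.00241) and Ccng1 at 1.11 (adjusted p = 0.00132). For the p53 targets list camera gave adjusted p = 2.61e-05 (0.283 with an estimated correlation). Of the NRF2 antioxidant genes, 9 of 18 rose and 9 did not pass (9 rose adjusted over the list alone), with Slc7a11 (2.70, adjusted p = 0.000615), Nqo1 (2.03, adjusted p = 0.00141) and Srxn1 (3.14, adjusted p = 0.00153) rising. For the NRF2 antioxidant list camera gave adjusted p = 2.61e-05 (0.283 with an estimated correlation). The number of called members was 10 for chemokines and 10 higher and 1 lower for pyroptosis with library totals, and 5 for p53 targets and 5 for NRF2 genes without control replicate 1. The number was 5 for NRF2 genes without control replicate 3, and 6 for pyroptosis and 5 for p53 targets without ASH replicate 2. Called members numbered 5 for pyroptosis and 5 for NRF2 genes without ASH replicate 3.

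Hepatocyte identity genes in ASH had 5 of 19 members lower (4 fell adjusted over the list alone, camera adjusted p = 0.00771, adjusted p = 0.494 with an estimated correlation). Urea cycle genes had 4 of 20 members lower (0 passed adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.698 with an estimated correlation). The urea cycle list was not called without control replicate 3 and without ASH replicate 1 (adjusted p = 0.00140 to 0.0733 overall). Nuclear oxidative phosphorylation had 8 of 21 members lower (10 fell adjusted over the list alone, camera adjusted p = 0.000832, adjusted p = 0.698 with an estimated correlation). Alcohol metabolism had 1 of 12 members higher and 4 lower (1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0349, adjusted p = 0.698 with an estimated correlation). Camera did not call it without ASH replicate 1 or 2 (adjusted p = 0.00481 to 0.0605 overall). Neutrophil markers had 3 of 17 members lower (0 passed adjusted over the list alone), the granule genes Camp (-5.28, adjusted p = 0.0188), Ltf (-4.34, adjusted p = 0.0335) and Elane (-3.50, adjusted p = 0.0380), whose libraries overlapped those of control. The adjusted p of Camp was over 0.05 with a replicate block, without control replicate 3 and without ASH replicate 1 or 3 (0.000404 to 0.0714 overall). For Ltf it was over 0.05 with a replicate block, without control replicate 3 and without ASH replicate 1, 2 or 3 (0.00514 to 0.151 overall). For Elane it was over 0.05 with a replicate block, without control replicate 1 or 3 and without ASH replicate 1 or 3 (0.0113 to 0.142 overall). Without control replicate 3 their log2 fold changes were -3.43, -2.21 and -2.23. Cholangiocyte markers had 1 of 12 members higher, Krt23 (3.24, adjusted p = 0.00325), and cell cycle genes 1 of 26 members higher (0 passed adjusted over the list alone), Ccnd1 (1.22, adjusted p = 0.0390). The adjusted p of Ccnd1 was over 0.05 without control replicate 1 or 2, without ASH replicate 2 or 3 and without AH replicate 1 (0.0101 to 0.119 overall). Circadian clock genes had 4 of 17 members higher and 8 lower (4 rose and 9 fell adjusted over the list alone), with Arntl (3.15, adjusted p = 0.00205), Clock (1.51, adjusted p = 0.00467), Npas2 (6.34, adjusted p = 0.0130) and Nfil3 (1.11, adjusted p = 0.00225) rising and Per3 falling (-2.86, adjusted p = 0.00427). Camera did not call the neutrophil, cholangiocyte, cell cycle and clock lists (adjusted p = 0.228, 0.228, 0.155 and 0.228). In the libraries in which these hepatocyte genes were lower, 18 of 21 matrix, 13 of 14 endothelial and 11 of 18 macrophage genes were higher. The number of called members was 2 higher and 4 lower for hepatocyte identity, 1 for the urea cycle, 1 for oxidative phosphorylation, 3 for cholangiocyte markers, 2 for cell cycle and 4 higher and 5 lower for circadian clock with library totals, and 1 for the urea cycle, 5 for oxidative phosphorylation and 0 for cell cycle without control replicate 1. The number was 3 for hepatocyte identity, 2 for the urea cycle, 3 for oxidative phosphorylation, 8 for neutrophil markers and 0 for cell cycle without control replicate 2, and 3 for hepatocyte identity, 0 for the urea cycle, 5 for oxidative phosphorylation, 0 for neutrophil markers, 2 for cholangiocyte markers and 3 for cell cycle without control replicate 3. Called members numbered 0 for cell cycle without AH replicate 1, and 8 for the urea cycle, 8 for alcohol metabolism and 3 for cholangiocyte markers without AH replicate 2. It was 1 higher and 0 lower for neutrophil markers and 1 higher and 1 lower for cell cycle without ASH replicate 1, and 2 for hepatocyte identity, 1 for the urea cycle, 3 for oxidative phosphorylation, 3 for alcohol metabolism and 0 for cell cycle without ASH replicate 2. The number was 3 for hepatocyte identity, 1 for the urea cycle, 2 for oxidative phosphorylation, 2 for alcohol metabolism, 0 for neutrophil markers and 0 for cell cycle without ASH replicate 3.

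Camera called 17 of 36 lists in ASH, 10 higher and 7 lower, and with an estimated correlation 1, cholesterol synthesis and uptake. Fry found 14 lists moving one way and 32 changing in either direction. Of the lists camera did not call, bile acid genes had 4 of 19 members higher and 5 lower, one-carbon genes 2 of 18 members higher and 7 lower, xenobiotic metabolism 4 of 25 members higher and 1 lower, fatty acid oxidation 5 of 22 members higher and 1 lower, acute phase proteins 5 of 22 members higher, ER stress 5 of 20 members higher, apoptosis and necroptosis 5 of 20 members higher and 2 lower and immediate early genes 6 of 17 members higher and 2 lower. Interferon-stimulated genes had 2 of 22 members higher and 1 lower, glycolysis and gluconeogenesis 3 of 19 members higher and 2 lower, heat shock proteins 1 of 12 members higher, lymphocyte markers 1 of 17 members lower, red blood cell genes 3 of 5 members higher and 1 lower, exocrine pancreas 2 of 2 members lower, adipose tissue 1 of 5 members higher and 2 lower and gut epithelium 2 of 3 members lower. None of 13 mitochondrially encoded genes passed edgeR's test, 0 had an unadjusted p under 0.05 with a lower value, and DESeq2 called 0 lower. The number of called members was 3 higher and 4 lower for one-carbon metabolism, 9 higher and 0 lower for xenobiotic metabolism, 10 higher and 1 lower for fatty acid oxidation, 8 higher and 1 lower for apoptosis, 5 higher and 0 lower for glycolysis and 4 for heat shock proteins with library totals, and 3 for xenobiotic metabolism, 2 for acute phase proteins, 2 for ER stress, 2 for apoptosis, 5 for immediate early genes, 0 for glycolysis and 1 for red blood cell without control replicate 1. The number was 5 for immediate early genes, 1 for glycolysis and 0 for red blood cell without control replicate 2, and 5 for one-carbon metabolism, 2 for acute phase proteins, 4 for apoptosis and 1 higher and 1 lower for heat shock proteins without control replicate 3. Called members numbered 3 for apoptosis without AH replicate 1, and 14 for xenobiotic metabolism and 2 for heat shock proteins without AH replicate 2. It was 4 for apoptosis without AH replicate 3, and 2 higher and 1 lower for acute phase proteins, 7 for interferon genes, 3 for glycolysis and 1 higher and 1 lower for heat shock proteins without ASH replicate 1. The number was 3 for acute phase proteins, 3 for apoptosis, 2 for glycolysis and 0 for red blood cell without ASH replicate 2, and 5 for one-carbon metabolism, 2 for apoptosis, 4 for immediate early genes, 0 for glycolysis and 1 higher and 1 lower for heat shock proteins without ASH replicate 3. Leaving out 1 library gained camera calls in ASH for immediate early without control replicate 1, neutrophil, lymphocyte, fatty acid oxidation and ER stress without control replicate 2, cell cycle and red blood cell without control replicate 3, immediate early without ASH replicate 1, ER stress without ASH replicate 2, acute phase proteins and ER stress without ASH replicate 3, xenobiotic metabolism and mitochondrially encoded without AH replicate 2, and immediate early without AH replicate 3. The other alternatives gained neutrophil, ER stress, immediate early, cell cycle and mitochondrially encoded. Adjusted over the list alone the counts of the lists camera did not call differed for bile acid synthesis and transport (4 rose and 7 fell), one-carbon metabolism (3 rose and 7 fell), xenobiotic metabolism (4 rose), acute phase proteins (3 rose), apoptosis (6 rose and 3 fell), immediate early (10 rose and 2 fell), lymphocyte (0 passed) and red blood cell (4 rose and 1 fell). The medians of interferon-stimulated, heat shock and one-carbon genes were of the opposite sign with library totals, and the interferon and adipose medians (-0.04 and 0.39) differed in sign from their means (0.07 and -0.05), with camera lower for adipose tissue without passing.

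AH against ASH asked what a weekly binge replacing other ethanol did. Casp4 averaged 11.2 ± 4.67 CPM in AH and 3.77 ± 0.449 in ASH, with the 3 AH libraries above the 3 ASH libraries, and did not pass edgeR's quasi-likelihood test (mean ± SD, n = 3 each, log2 fold change 1.57 ± 0.40 SE, adjusted p = 0.235). Its adjusted p was 0.0154 by DESeq2, and without AH replicate 2 its log2 fold change was 1.88 (adjusted p = 0.0234). Its adjusted p ran from 0.0154 to 0.721 overall. Casp1 (0.52 ± 0.46, adjusted p = 0.595), Pycard (0.99 ± 0.52, adjusted p = 0.396), Nlrp3 (0.44 ± 0.40, adjusted p = 0.608), Gsdmd (0.18 ± 0.15, adjusted p = 0.569), Il1b (-0.11 ± 0.44, adjusted p = 0.922) and Il18 (-0.10 ± 0.23, adjusted p = 0.855) did not pass. Gsdmd was 0.33 without ASH replicate 2 and 0.06 without ASH replicate 3, and Casp1 was 0.34 without ASH replicate 2. Library totals gave 0.85 for Casp1, 0.74 for Nlrp3 and 0.50 for Gsdmd, and upper-quartile factors 0.30 for Gsdmd.

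By edgeR's quasi-likelihood test 0 of 15228 genes passed in AH against ASH, the lowest adjusted p was 0.235, and 2212 genes had an unadjusted p under 0.05, 1153 higher and 1059 lower, where chance gives 761. A split with ASH replicate 1 kept AH replicates 1 and 3 together (2234), so it cannot judge the excess. DESeq2 called 398 genes, 222 higher and 176 lower. Without AH replicate 2 edgeR called 846, 401 higher and 445 lower, and without ASH replicate 1 it called 3. The groups did not overlap in 18.7% of genes, where chance gives 10%. Library totals put the median of all genes 0.33 higher and upper-quartile factors 0.11 higher.

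None of 12 cholangiocyte and progenitor markers passed edgeR's test over all genes, and 11 rose adjusted over the list alone. Of them 11 were higher at an unadjusted p under 0.05, DESeq2 called 9 higher, and without AH replicate 2 edgeR called 11. For the cholangiocyte list camera gave adjusted p = 3.40e-10 (0.433 with an estimated correlation). Epcam averaged 1.76 ± 0.523 CPM in ASH and 14 ± 10.3 in AH (log2 fold change 3.00 ± 0.66 SE, adjusted p = 0.235, and 3.51, adjusted p = 0.00326 without AH replicate 2, 0.00103 to 0.721 overall), and Cd24a (2.77, adjusted p = 0.235) and Pkhd1 (1.45, adjusted p = 0.235) lay higher in 3 of 3 AH libraries. For monocyte and macrophage markers 0 passed, 4 rose adjusted over the list alone, 7 were higher at an unadjusted p under 0.05 and DESeq2 called 4. For the monocyte list camera gave adjusted p = 6.89e-06 (0.433 with an estimated correlation). Cx3cr1 and Ms4a7 were at log2 2.45 and 2.26 (both adjusted p = 0.235), and without AH replicate 2 the macrophage count was 4. For neutrophil markers 0 passed, 4 rose adjusted over the list alone, 9 were higher at an unadjusted p under 0.05 and DESeq2 called 2. For the neutrophil list camera gave adjusted p = 4.85e-07 (0.433 with an estimated correlation). The granule genes Elane (3.97), Camp (4.44) and Mpo (3.98) were higher in 3 of 3 AH libraries (adjusted p = 0.254 to 0.271). With all controls mainly ASH differed from control (neutrophil median -1.95, AH 0.47). The chemokine genes Cxcl5 and Cxcl1 were at log2 3.50 and -1.39 (both adjusted p = 0.235). Of the genes of this paragraph DESeq2 called all but Mpo, and without AH replicate 2 edgeR called all but Elane, Camp, Mpo and Cxcl1. Cxcl5 was also called without a filter.

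For pyroptosis and inflammasome genes 0 passed in AH against ASH, 2 rose adjusted over the list alone, 4 were higher at an unadjusted p under 0.05, DESeq2 called 2 higher, and edgeR called 2 without AH replicate 2. For the pyroptosis list camera gave adjusted p = 0.00755 (0.443 with an estimated correlation). Camera did not call it without ASH replicate 1 (adjusted p = 0.00148 to 0.0946 overall). Panx1 had a log2 fold change of 1.39 ± 0.35 (adjusted p = 0.235). For xenobiotic metabolism 0 passed, 1 fell adjusted over the list alone, 7 were lower at an unadjusted p under 0.05, DESeq2 called 2 lower, and without AH replicate 2 edgeR called 19. For the xenobiotic list camera gave adjusted p = 1.10e-10 (0.433 with an estimated correlation). The cytochrome P450 genes Cyp3a13 (-1.10, adjusted p = 0.235) and Cyp2f2 (-1.18, adjusted p = 0.256) and Por, which passes electrons to these enzymes (-1.35, adjusted p = 0.273), were lower in 3 of 3 AH libraries. For endothelial markers 0 passed, 0 passed adjusted over the list alone, 7 were lower at an unadjusted p under 0.05 and DESeq2 called 1. For the sinusoidal list camera gave adjusted p = 4.85e-07 (0.433 with an estimated correlation). Clec4g, a lectin of sinusoidal endothelium, had a log2 fold change of -1.43 (adjusted p = 0.254), and Kdr, a receptor for vascular endothelial growth factor, of -1.27 (adjusted p = 0.273). DESeq2 called Panx1, Cyp3a13, Cyp2f2 and Clec4g, and without AH replicate 2 edgeR called Panx1, Cyp3a13, Cyp2f2 and Por, with Por at -2.20.

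Camera called 26 of 36 lists between AH and ASH, 10 higher and 16 lower, and none with an estimated correlation, where the lowest adjusted p was 0.433. Leaving out 1 library lost the calls of pyroptosis, lymphocyte, stellate cell and matrix, fatty acid synthesis, chemokines, ER stress, one-carbon metabolism, heat shock proteins, red blood cell, mitochondrially encoded and adipose tissue without ASH replicate 1, male-biased liver, red blood cell and adipose tissue without ASH replicate 2, heat shock proteins without ASH replicate 3, stellate cell and matrix, one-carbon metabolism and adipose tissue without AH replicate 1, lymphocyte, fatty acid synthesis and heat shock proteins without AH replicate 2, and stellate cell and matrix, red blood cell and adipose tissue without AH replicate 3. Library totals lost lymphocyte, stellate cell and matrix and chemokines, and the CPM filter lymphocyte. Leaving out 1 library gained alcohol metabolism and immediate early without control replicate 1, immediate early without control replicate 2, immediate early without control replicate 3, interferon and immediate early without ASH replicate 1, alcohol metabolism without ASH replicate 2, Kupffer cell and alcohol metabolism without AH replicate 2, and circadian clock and immediate early without AH replicate 3. The other alternatives gained alcohol metabolism, immediate early, female-biased liver and circadian clock. Fry found 0 lists moving one way and 3 changing in either direction. Without AH replicate 2 the number of members called was 7 for stellate cell and matrix, 6 for male-biased, 6 for cholesterol synthesis, 5 for urea cycle and 5 for bile acid genes, against 0 with all libraries. The medians of Kupffer, clock, female-biased, glycolysis, heat shock, one-carbon, oxidative phosphorylation and p53 genes changed sign with library totals, and those of glycolysis and p53 genes also with upper-quartile factors. The glycolysis median was -0.04 with a mean of 0.03, and the p53 median was -0.02 while camera's direction was higher, without passing.

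Of 5055 genes called in AH and 4668 in ASH against control, 3261 were called in the same direction in both, 1726 higher and 1535 lower, and 0 in opposite directions, where independent calls would share 778. Both comparisons share 3 controls, too few to split. In 50 simulations without group effects at most 2 genes passed per direction, so sharing 0 is no test. Their Pearson r across genes was 0.526 (0.5 to 0.548) against 0.853 observed, and covariance 0.0807 (0.0746 to 0.0882) against 1.19. Genes are not independent replicates. The shared count was 2038 without control replicate 1, 2030 without control replicate 2, 2021 without ASH replicate 3 and 1887 without AH replicate 1, and without AH replicate 2 it was 3383 with 11 genes in opposite directions.

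**Figure D4:**
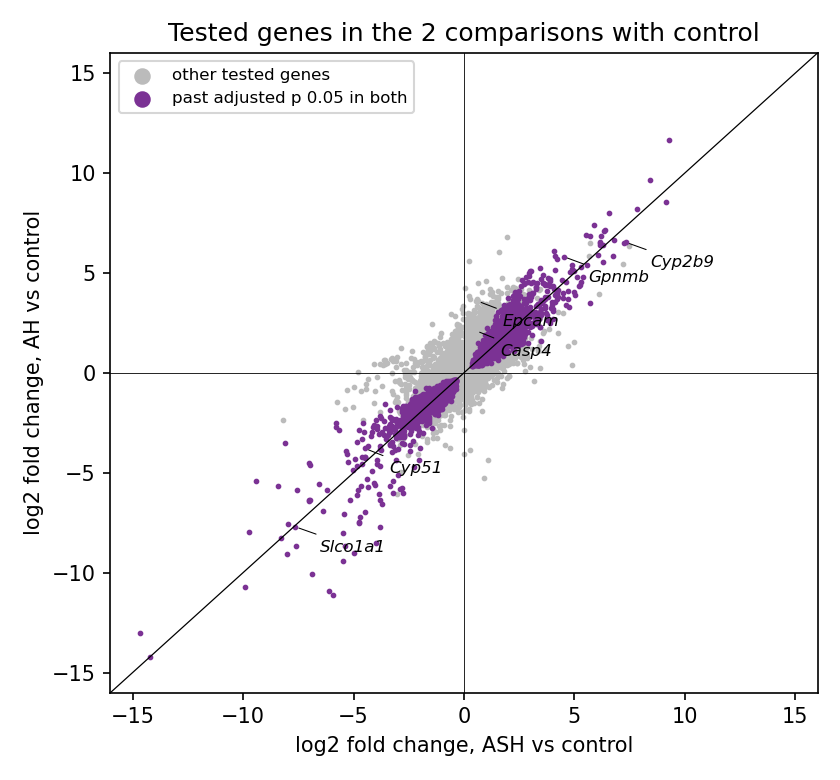
Log2 fold change of each tested gene in ASH against control (horizontal) and in AH against control (vertical), with the fitted value for genes at 0 reads in a group. Cyp51 lay at -4.50 and -3.78, Epcam at 0.60 (0.93 with library totals and 0.39 without ASH replicate 3) and 3.60, and Casp4 at 0.53 and 2.11.

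The authors' table lists 4972 genes, all with the authors' p under 0.05 in AH against control. In it 2845 genes had the authors' false discovery rate under 0.05 in AH against control, 2066 in ASH against control and 0 in AH against ASH. Of 4901 genes in both sources, the sign was the same in 100% for AH against control, 99.8% for ASH against control and 99.1% for AH against ASH. The authors' ratio of Casp4 was 3.27 in AH against control (rate 0.0559) and 2.52 in AH against ASH (rate 0.393), and that of Nlrp3 2.66 (rate 0.0321) in AH against control. Gsdmd and Casp1 are not among the genes of that table.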

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

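The tests of lower depth and of the other splits were chosen before their results were seen, and all other tests given here were chosen after the result was seen.

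Genes of cholesterol synthesis and uptake were lower in both AH and ASH. Composition scaling is argued against, since with library totals the median log2 fold change nearer 0 of both comparisons was -2.21, with 21 members called lower and 1 higher in AH and 22 lower in ASH. A sterol load stays undecided, with a median of -0.35 over 10 LXR targets in AH that had 2 members higher and 2 lower and a median that flips sign with library totals, and the labels do not give the diet of each group. Another time of day at sampling stays undecided, as no test tied the clock to cholesterol genes. The clock phases differed by 2.82 in AH and 3.00 in ASH in median log2 fold change, and ethanol or feeding could also shift them. Ethanol itself stays among the open explanations, as untested, and so does the sequencing lane.

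Most male-biased liver genes were lower in AH and ASH, and of 12 female-biased genes 5 were called higher in AH and 6 in ASH. Female animals are argued against, since no library had over 7 Xist reads and every ASH and AH library had at least 2340 reads of Y-linked genes. Reads shared among paralogs are argued against as the whole cause, since the 5 male-biased members outside multigene families were all called lower, with a median of -2.80 in the comparison nearer 0. Weaker growth hormone signalling stays undecided, with a median of -0.88 over 7 growth hormone targets in ASH and -1.16 in AH. In each, 3 were called lower (Igf1, Igfals and Ghr), fewer than the test asked for. The direct targets Socs2 and Cish did not pass, and Bcl6, which growth hormone represses, was called lower, opposite to what weaker signalling predicts. Ethanol feeding in the design stays open as its source, as untested.

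AH replicate 2 lay between ASH and the other AH libraries, at 0.284 of the way from ASH (0) to AH replicates 1 and 3 (1). Lower depth is argued against, since thinning AH replicates 1 and 3 to its depth moved them by at most 0.0136 of the way. A mislabelled ASH library stays undecided, as distance cannot tell it from an AH library near ASH. On average AH replicate 2 lay 0.669 from ASH libraries, and these up to 0.728 from each other. Its mean distance to control was 1.07, the smallest of the 6 ASH and AH libraries. No biological explanation was tested, and the labels were kept.

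With 10 splits the share as large cannot be under 0.1. Each other split mixes the groups, widening the spread, so it is no chance reference. In AH against control the real and highest other splits called 5055 and 0 genes (1 of 10 as large). In ASH against control they called 4668 and 1 (1 of 10), and in AH against ASH 0 and 1 (10 of 10). At an unadjusted p under 0.05 AH against ASH had 2212 and 2234 (2 of 10). The others placed AH replicate 2 with ASH replicates 1 and 3, then 2 and 3. For gene lists called by camera the real and highest other counts were 23 and 24 in AH against control (2 of 10 as large), 17 and 21 in ASH against control (6 of 10) and 26 and 21 in AH against ASH (1 of 10).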

How the results depend on the processing

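Counts of list members under other settings, given with the lists, were added after the data were seen. Of 3761 values of named genes under an alternative, 3629 kept their direction and side of the threshold, 98 no longer passed, 26 newly passed and 8 reversed. The cause was not tested, except where a stricter threshold or fewer libraries give it.

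For AH vs control 7945 genes passed with library totals, 2014 at an adjusted p under 0.01, 3089 with at least 2-fold change, and 2338 to 5743 without 1 library. For ASH vs control it was 1644 at an adjusted p under 0.01, 2694 with at least 2-fold change, and 2716 to 5298 without 1 library. For AH vs ASH it was 398 by DESeq2, 8 without a filter, 2 with a replicate block, and 0 to 846 without 1 library. The replicate numbers do not pair the libraries (same-number correlations of -0.154 to 0.216).

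Gene lists called with an estimated correlation numbered 1 in AH against control, 1 in ASH against control and 0 in AH against ASH. Fry found 32 in either direction in ASH against control, and 0 one way and 3 in either direction in AH against ASH. Without 1 library the lists called in AH against ASH numbered 17 to 28.

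In AH against ASH, Il1b was 0.00885 with upper-quartile factors, 0.16 with library totals and -0.47 to 0.14 without 1 library, and Il18 was 0.00810, 0.20 and -0.29 to 0.0131. The shared genes of AH and ASH numbered 2541 to 4194 under other scalings, tests, filters and fits. Alternatives that treat the lanes of control replicate 3 apart were not run, since the table holds 1 merged column. Depth limits what the 18697810 reads of AH replicate 2 can show.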
